A study of Mus musculus with 8 samples.

How the data were processed

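RNA was sequenced from mouse induced pluripotent stem (iPS) cells, which are cells reprogrammed to an embryonic stem cell-like state. Per the series' design text, the libraries came from 5 independent lines homozygous for the Polg substitution D257A, called mutator lines here, and from 3 wild-type lines of littermate embryos. Per the labels' protocols, total RNA was taken from cells kept on growth-arrested feeders with LIF and moved to gelatin for 1 passage beforehand to deplete the feeders. Groups and replicate numbers were taken from the sample titles.

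The deposited values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 column per library and 1 row per Ensembl gene ID, and STAR and Cufflinks were named in the submitters' processing notes. The row headers of the deposited FPKM table were those of Cufflinks. The versions, the genome build, the annotation, the strandedness and the read length were not given in the sources used here. The table had 37305 gene rows with 34369 distinct symbols. Rows of the 265 symbols found on more than 1 row were summed, and 31 NA cells in 23 rows were kept as missing. For positions and biotypes, 35447 of the gene IDs were found in GENCODE M21 (GRCm38), 27913 of them with the same symbol. All coordinates below are from GENCODE M21 by gene ID and are not the authors' own.

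The library depth was not recorded in the table, and FPKM are not counts, so no count test was applied. Low values were whole multiples of a gene-specific step. In mutator replicate 1 the step, estimated from 52 genes whose values stood in a 3:2 or 2:3 ratio between mutator replicates 1 and 2 (within 0.01 on the log2 scale), implied about 25700000 fragments. FPKM sums ranged from 753985 to 1780534 per library, and small RNA and tRNA genes made up 72.4% to 86.8% of them. FPKM of very short genes depend strongly on the length correction. For example, 59 genes with a median of 10 FPKM or more were listed at 0 in a library, and 0 of these had an exonic length of 500 bases or more.

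Replicates were compared before they were averaged. Between mutator replicates 1 and 2, the squared difference in implied fragments, scaled to their sum, had a median 1.11 times that expected from fragment sampling. It was 4.01 to 17.24 times in the 12 other pairs within a group. The step of mutator replicate 1 was used for all libraries, so the expected values of the other pairs do not reflect their own depth. For genes of at least 500 bases and 20 implied fragments, mutator replicates 1 and 2 therefore differed no more than 2 sequencing runs of 1 library would. Their mean was used and they were counted as 1 sample, so the tests compared 4 mutator with 3 wild-type samples. The design fixed before the data were examined had counted all 8 libraries, and that fit is given as an alternative. Same-numbered samples of the 2 groups were not paired: the 3 correlations of their deviations from the group means were 0.013, -0.012 and 0.051.

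Genes with a mean of at least 1 FPKM over the 8 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over 11949 genes and a threshold of 0.05. Log2 changes are on this scale, mutator minus wild type, and understate the change of low genes. Means and SD are of FPKM. Gene lists written before the data were examined were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of 36 lists, 35 had at least 3 tested members; the 27 genes found of the two-cell-like list had no tested member, the highest mean being 0.51 FPKM for Pramel7. Single values and list means were compared by exact two-sided permutation tests, for which 4 against 3 samples allow no p below 0.057. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for the rest.

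The fit was tested on simulated data made from the real means and spread, 4 against 3 samples and 11949 genes, with 200 genes changed. At a log2 change of 1 it recovered 31.5% with 6 false calls. At 2 it recovered 91% with 9 false calls, at 3 it recovered 93.5% with 4 false calls, and with no change it called 0 genes. The noise was drawn independently for each gene, so false calls from variation that genes share within a sample were not tested.

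The genes named were chosen by a rule written before the data were examined: Polg; the 12 higher and 12 lower called genes with the largest log2 change whose 5 mutator values all lay on one side of the 3 wild-type values, leaving out predicted genes and pseudogenes; of each list described, up to 4 called members with the smallest p, or up to 2 as values where none was called; the 13 mtDNA-encoded protein genes as a group; and Xist and Ddx3y per library. Genes outside the rule are marked as such, and 1 gene the rule selects is not reported here. The alternatives covered the pseudocount, the filter, TPM rescaling, median-of-ratios and quantile normalization, the treatment of repeated symbols, the trend, array weights, a replicate block, feeder marker expression as a covariate, sex chromosome genes and leaving out each replicate. Others, added after the data were seen, are named as such in the closing section.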

Results

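The data were FPKM of 8 RNA-seq libraries from mouse iPS cells: 5 from mutator lines, homozygous for the D257A substitution in Polg, and 3 from wild-type lines of littermate embryos. Polg encodes the catalytic subunit of the mitochondrial DNA polymerase, and the substitution removes its proofreading activity, so that mtDNA collects mutations. The comparison asks how transcript levels differ between mutator and wild-type iPS cells. Between 11334 and 12078 genes per library had at least 1 FPKM. Mutator replicates 1 and 2 differed by no more than sampling noise, although 5 independent lines were described. The headers of their columns share a code (u6 and u6_1), while those of mutator replicates 3 to 5 are u11, mG and u2, so they may be 1 line. They were counted as 1 sample (n = 4 mutator and n = 3 wild-type samples). The headers of the wild-type columns share a number (7a, 7b and 7c), so these lines may come from 1 embryo, in which case embryo and genotype are confounded. The first principal component held 32% of the variance and separated the groups, with wild-type scores of -48 to -27.1 and mutator scores of 9.42 to 47.8.

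In the mutator cells, Hexa, for a lysosomal enzyme, Efemp1, for a matrix protein, and S100a13, for a calcium-binding protein, were among the genes with the largest increases. Transcripts for the DNA methyltransferase Dnmt3a, cyclin E1, the pluripotency factor Dppa2 and a block of zinc-finger genes were among the most decreased. Of 11949 genes tested, 895 changed (limma, Benjamini-Hochberg adjusted p below 0.05), 353 of them higher and 542 lower in mutator cells, and 399 by a log2 change of 1 or more. At an unadjusted p below 0.05 there were 3626 genes, where 597 would be expected by chance. Of the 895 genes, 797 were protein-coding, and 892 had all 5 mutator libraries on one side of the 3 wild-type libraries. The call itself favours such separation, so the 892 add no support to it. Among all genes tested, 28.5% had 4 mutator samples that did not overlap the 3 wild-type samples, against 5.7% by chance. The count rests on each wild-type line, falling to 5, 2 and 2 genes without wild-type replicates 1, 2 and 3. It fell to 5 without the mutator 1 and 2 pair, to 241 without mutator replicate 4 and to 581 without mutator replicate 5. It was 4 with no filter, 2 with the feeder list as covariate and 0 with Y-linked expression as covariate, but 2150 with median-of-ratios size factors and 3618 with array weights. Rescaling to TPM gave 1092 higher and 21 lower genes because it moved the median log2 change of all genes from -0.03 to 0.37. TPM divides by the FPKM sum of the library, of which small RNA and tRNA genes made up 72.4% to 86.8%. That sum rests mainly on short genes, whose FPKM depend strongly on the length correction. Calls under TPM include this shift, so that changes are best read relative to the median. On that relative scale the mitochondrial ribosomal, DNA replication and G1 to S lists described below had medians of -0.49, -0.58 and -0.52 under TPM.

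Polg itself did not differ detectably. It is on chromosome 7 (79446231 to 79466362, ENSMUSG00000039176) and measured 9.48 ± 0.539 FPKM (SD, n = 3) in wild-type and 10.2 ± 1.93 FPKM (SD, n = 4) in mutator samples. The log2 change was 0.07 with a standard error of 0.18 (limma adjusted p = 0.81; exact two-sided permutation p = 0.743). A point substitution need not alter the transcript level, so this value checks the labels only weakly.

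**Figure D1:**
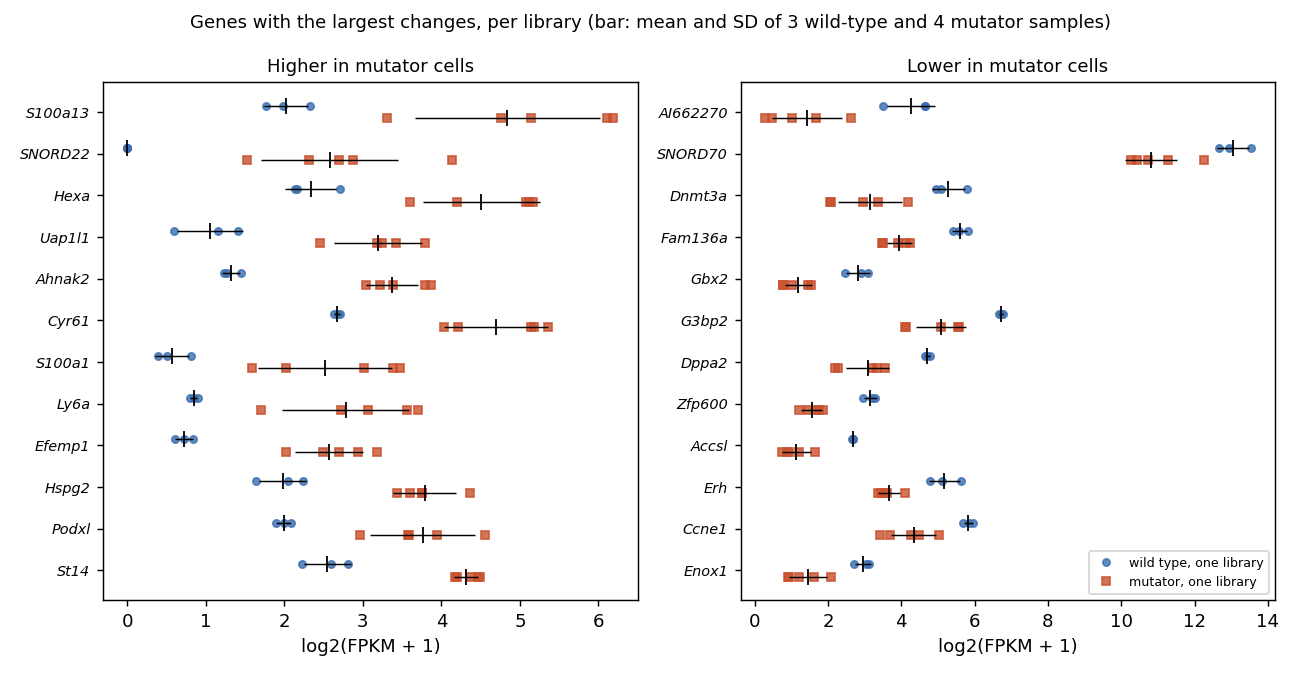
FPKM per library, as log2(FPKM + 1) on the horizontal axis, of the 12 higher and 12 lower genes with the largest changes. Circles are the 3 wild-type and squares the 5 mutator libraries, and bars give the mean and SD of 3 wild-type and 4 mutator samples. For each gene the 5 squares lie on one side of the 3 circles, as the rule that chose the genes required.

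Among the increased genes, S100a13 and S100a1, neighbouring genes for calcium-binding proteins on chromosome 3, showed large differences. S100a13 (90514435 to 90524581) measured 3.12 ± 0.817 FPKM (n = 3) in wild-type and 34.8 ± 25.7 FPKM (n = 4) in mutator samples, a log2 change of 2.81 with a standard error of 0.56 (limma adjusted p = 0.034). S100a1 rose by 1.94 on the log2 scale, from 0.495 to 5.47 FPKM. Because the 2 genes lie side by side, 90511034 to 90514392 for S100a1, and the strand setting is not known, their reads might not be fully separable. Hexa, which encodes a subunit of the lysosomal enzyme hexosaminidase, rose from 4.12 ± 1.2 to 24 ± 11.6 FPKM, 5.82-fold. Uap1l1 rose 7.64-fold and Ahnak2 6.4-fold. Cyr61, a member of the feeder marker list, Efemp1, Hspg2 (perlecan) and Podxl (podocalyxin) rose 5.0-fold, 7.89-fold, 4.43-fold and 4.59-fold. The endoderm marker mean described below was also above all wild-type samples in 4 of 4 mutator samples. The feeder marker mean was so in 3 of 4. Ly6a, the gene for the surface antigen Sca-1, rose from 0.799 ± 0.0568 to 6.66 ± 3.83 FPKM, and St14, a membrane serine protease gene, from 4.92 ± 1.19 to 19 ± 2.14 FPKM. The small nucleolar RNA SNORD22 was listed at 0 in the 3 wild-type libraries and at 16.6, 5.46, 1.89, 3.97 and 6.36 FPKM in mutator replicates 1 to 5.

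Dnmt3a, which encodes a de novo DNA methyltransferase (chromosome 12, 3806007 to 3914443), fell from 39.2 ± 13.4 FPKM (n = 3) in wild-type to 9.11 ± 5.88 FPKM (n = 4) in mutator samples, a log2 change of -2.13 with a standard error of 0.46 (limma adjusted p = 0.037). The noncoding transcript AI662270 fell from 19.5 ± 7.98 to 2.18 ± 2.16 FPKM and had the lowest log2 change of the named genes, -2.84. Dppa2, expressed in pluripotent cells and early embryos, fell from 25.2 ± 1.21 to 7.95 ± 3.01 FPKM, and the homeobox gene Gbx2 from 6.2 ± 1.54 to 1.34 ± 0.572 FPKM. Ccne1, which encodes cyclin E1, fell from 55.9 ± 5.01 to 20.5 ± 8.75 FPKM. G3bp2, for a stress granule protein, fell from 104 ± 4.05 to 35.5 ± 14.3 FPKM. Fam136a, for a mitochondrial protein, Zfp600, Accsl, Erh and Enox1 also fell. Their log2 changes were -1.65, -1.59, -1.55, -1.51 and -1.49. The small nucleolar RNA SNORD70, summed over 2 rows, fell from 8728 ± 2810 to 1992 ± 1130 FPKM, a scale that very short transcripts reach through the length correction. Within the pair counted as 1 sample, SNORD70 measured 4856 FPKM in mutator replicate 1 and 2463 FPKM in mutator replicate 2.

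Zfp600 lies in a block of related zinc-finger genes on distal chromosome 4 that was lower as a whole, a region singled out after its values were seen. From 145510759 to 147848366 (GENCODE M21, GRCm38) the block holds 21 tested protein-coding genes with zinc-finger gene names or predicted-gene names, and 19 of them fell and 0 rose in limma. All 21 had a log2 change below 0 (20 with the length and GC trend removed), with a median of -1.37 and a range of -1.95 to -0.44. Under TPM all 21 were below 0 at a median of -0.89, but 4 were called. With no filter 1 was called, and 0 were with the replicate block, the feeder covariate or the Y-linked covariate, although all 21 stayed below 0 at medians of -1.52, -1.19 and -1.55. Without any 1 of the wild-type replicates, or without the mutator 1 and 2 pair, 0 of 21 were called, at medians of -1.39 to -1.33. Gm13247 fell from 30.3 to 37.4 FPKM in the 3 wild-type libraries to 5.59 to 9.56 FPKM in the 5 mutator libraries, Gm13145 from 44.1 to 48.6 FPKM to 12 to 17.1 FPKM, and Rex2, a zinc-finger gene, by 1.27 on the log2 scale. The 41 tested protein-coding genes in the 3 Mb on either side had a median of 0.25, with 1 lower and 4 higher. The genes of the block are close paralogs, so the value of a single one is uncertain where reads were shared.

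**Figure D2:**
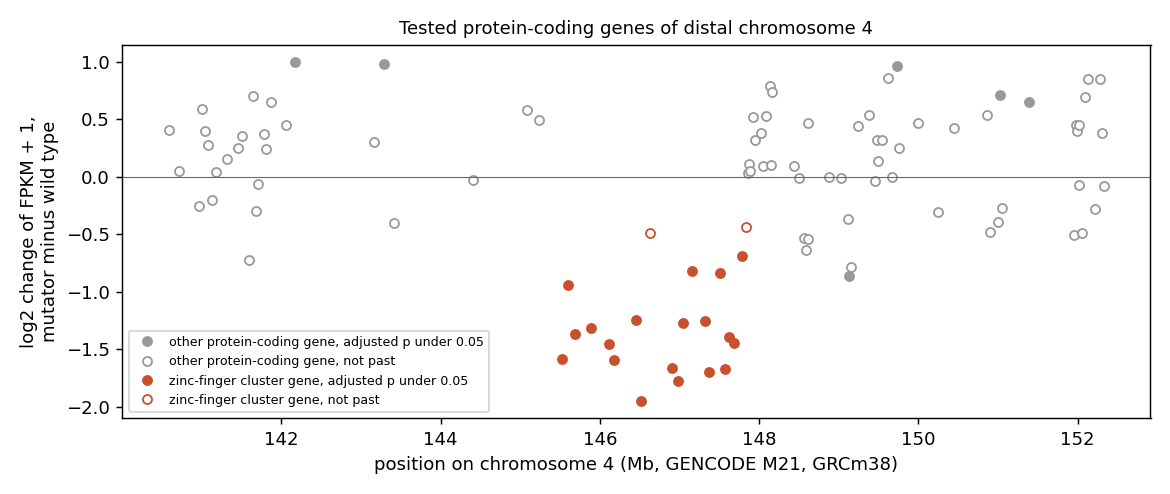
Log2 change, mutator minus wild type, of tested protein-coding genes against their position on chromosome 4 in Mb (GENCODE M21, GRCm38). Coloured circles are the 21 genes of the zinc-finger block and grey circles are other genes, filled where the limma adjusted p was below 0.05; the block lies between -1.95 and -0.44 while the genes on either side have a median of 0.25.

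Some genes of mitochondrial translation and mtDNA maintenance were lower in mutator cells. Of 75 mitochondrial ribosomal protein genes tested, 12 fell, 0 rose and 63 did not pass (33 lower adjusted over the list alone). Under TPM 0 fell, with median-of-ratios size factors 35 and with array weights 41. The list had a median log2 change of -0.59 (camera adjusted p = 1.7e-10; adjusted p = 0.87 with an estimated correlation). Mrpl20 fell from 27.8 ± 3.89 to 9.42 ± 1.73 FPKM, and Mrpl40, Mrps22 and Mrpl18 fell by 1.15, 1.05 and 1.31 on the log2 scale. The list mean lay below all 3 wild-type samples in 4 of 4 mutator samples (exact two-sided permutation p = 0.057, the smallest possible), though by 0.01 in mutator replicate 5, at 3.76 against 3.77 in wild-type replicate 3. Of 24 genes for mtDNA replication and transcription, 3 fell and 21 did not pass (8 lower and 1 higher adjusted over the list alone). The list median was -0.4 (camera adjusted p = 0.0025, adjusted p = 0.87 with an estimated correlation, exact permutation p = 0.057). Under TPM it was 0.0, or -0.36 relative to the median of all genes. The genes that fell were Ssbp1, the mitochondrial single-strand DNA-binding protein gene, from 47.5 ± 7.13 to 21.8 ± 4.11 FPKM, Fen1, a flap endonuclease gene, and 1110002N22Rik. Of 39 genes for nucleotide pool enzymes 4 fell (9 lower adjusted over the list alone), among them Dtymk, Ppat and Umps, at log2 changes of -1.0, -1.16 and -1.1. Under TPM 0 of these 39 and 0 of the 24 fell, and with median-of-ratios size factors 11 and 8. The median of the nucleotide pool list was -0.51 (camera adjusted p = 0.00044; adjusted p = 0.87 with an estimated correlation; exact permutation p = 0.114). The feeder fibroblast marker mean lay above all wild-type samples in 3 of 4 mutator samples. This mean log2 value was 3.71 and 3.76 in the mutator 1 and 2 pair and in mutator replicate 3. It was 2.47 and 2.7 in mutator replicates 4 and 5, and 2.17 to 2.6 in wild-type samples.

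Few genes of the respiratory chain itself passed. Of 13 mtDNA-encoded protein genes, 12 did not pass and the list median was 0.08 (camera adjusted p = 0.57). The abundant ones went both ways, and 0 of these 7 passed. mt-Co1, mt-Nd1 and mt-Cytb measured 5332 ± 1150, 2650 ± 491 and 1271 ± 271 FPKM in mutator samples and 6579 ± 1030, 3725 ± 524 and 1918 ± 374 FPKM in wild-type samples, with limma adjusted p of 0.55, 0.3 and 0.22. mt-Nd2, mt-Nd4, mt-Nd5 and mt-Nd6 measured 1180 ± 287, 656.6 ± 60, 1092 ± 295 and 723.9 ± 228 FPKM in mutator and 1025 ± 226, 561.4 ± 72.1, 865.5 ± 210 and 567.2 ± 175 FPKM in wild-type samples, with limma adjusted p of 0.7, 0.53, 0.53 and 0.51. mt-Nd4l was called higher (also the 1 adjusted over the list alone), from 1.04 ± 0.00928 to 2.38 ± 0.315 FPKM, but measured 1.25 FPKM in mutator replicate 1 and 2.86 FPKM in mutator replicate 2. It and mt-Atp6, mt-Atp8, mt-Co2, mt-Co3 and mt-Nd3 had 1.04 to 25.1 FPKM in the wild-type mean, far below the other mtDNA genes, so their values are uncertain where reads are shared with near-identical nuclear copies. Of 17 nuclear ATP synthase genes 1, Atp5k, fell from 94.7 ± 12 to 53 ± 4.89 FPKM (3 lower adjusted over the list alone). The list median was -0.43 (camera adjusted p = 0.041, adjusted p = 0.87 with an estimated correlation, exact permutation p = 0.171). Under TPM it was 0.08, or -0.29 relative to the median of all genes. Uqcrh was the 1 gene to fall of 26 for complexes II to IV (1 adjusted over the list alone; camera adjusted p = 0.06) and Ndufa5 the 1 of 36 for complex I (1 adjusted over the list alone; camera adjusted p = 0.13).

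**Figure D3:**
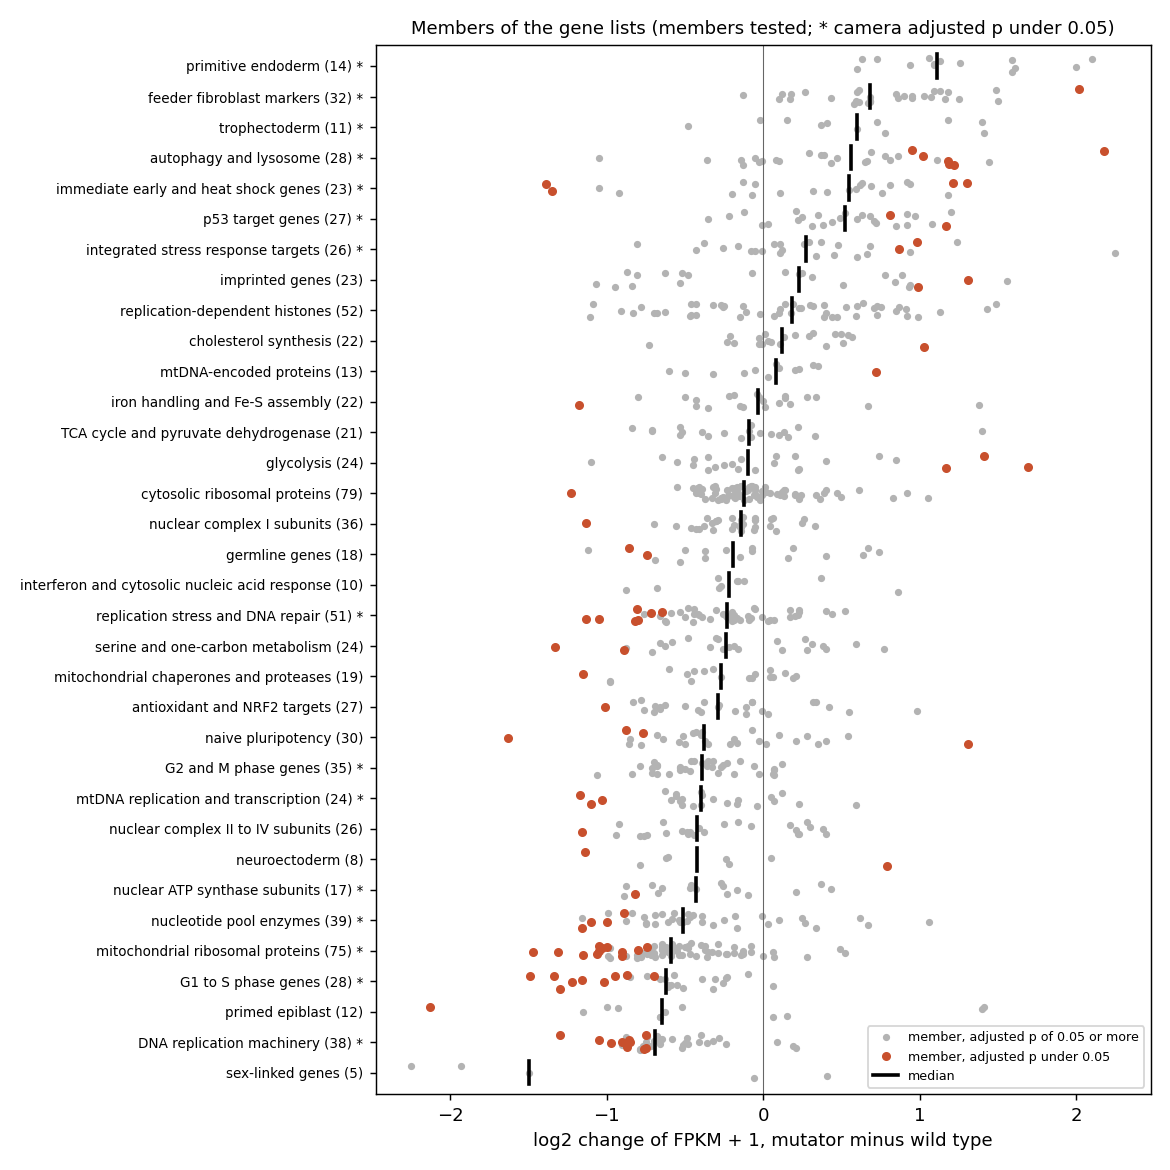
Log2 change of every tested member of the lists with 5 or more tested members, mutator minus wild type, with list names and tested members on the vertical axis. Dots are genes, coloured where the adjusted p was below 0.05, black bars are list medians and asterisks mark lists called by camera at the preset correlation; the DNA replication, G1 to S and mitochondrial ribosomal lists have medians of -0.69, -0.62 and -0.59, and no list was called with an estimated correlation.

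Some DNA replication and G1 to S phase genes were also lower. Of 38 DNA replication genes 10 fell and 28 did not pass (25 lower adjusted over the list alone). The median was -0.69 (camera adjusted p = 2.4e-09; adjusted p = 0.87 with an estimated correlation). Pcna, the sliding clamp of DNA polymerases (chromosome 2, 132249162 to 132253314), fell from 94.8 ± 21 to 38.3 ± 9.17 FPKM, and Rpa2, Rfc4 and Prim1 fell by 1.05, 0.85 and 0.86 on the log2 scale. Of 28 G1 to S phase genes, 2 of them also in the DNA replication list, 9 fell and 19 did not pass (19 lower adjusted over the list alone). Under TPM 0 genes of either list fell. With median-of-ratios size factors 19 DNA replication and 13 G1 to S genes did, and with array weights 27 and 17. The G1 to S median was -0.62 (camera adjusted p = 8.7e-08; adjusted p = 0.87 with an estimated correlation). Besides Ccne1 and Pcna, those that fell included Ccne2, for cyclin E2, from 10.7 ± 0.766 to 4.05 ± 0.807 FPKM, and Slbp, for the histone stem-loop binding protein, from 56 ± 3.96 to 22.1 ± 6.22 FPKM. Both list means lay below all wild-type samples in 4 of 4 mutator samples (exact two-sided permutation p = 0.057 for each, the smallest possible).

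Of 51 genes for replication stress and DNA repair 7 fell (11 lower adjusted over the list alone), among them Fancl, Hus1, Tipin and Brca1 at log2 changes of -1.13, -0.8, -1.05 and -0.72. The list median was -0.23 (camera adjusted p = 0.0016, adjusted p = 0.87 with an estimated correlation, exact permutation p = 0.114). Under TPM it was 0.18, or -0.19 relative to the median of all genes. No member of 35 G2 and M phase genes passed in limma, over all genes or adjusted over the list alone (0 in each). At a mean of at least 5 FPKM 3 fell, with median-of-ratios size factors 10 and with array weights 13. Their median was -0.39 (camera adjusted p = 0.00047, adjusted p = 0.87 with an estimated correlation, exact permutation p = 0.114). Under TPM it was 0.1, or -0.26 relative to the median of all genes. Kif20b, a mitotic kinesin gene, measured 28.5 ± 2.07 and 16.4 ± 3.74 FPKM and Cdk1 60.7 ± 14.6 and 29.2 ± 10.6 FPKM in wild-type and mutator samples, with limma adjusted p of 0.054 and 0.057. Replication-dependent histone genes had 0 of 52 past the threshold, over all genes or adjusted over the list alone, and a median of 0.19 (camera adjusted p = 0.76). Their list mean ranged from 2.97 to 4.61 among the wild-type samples alone. The feeder marker list was higher in 3 of the 4 mutator samples than in all wild-type samples and may confound these lists as well.

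Some lysosomal genes and p53 targets were higher. Of 28 autophagy and lysosome genes 6 rose and 22 did not pass (9 higher and 1 lower adjusted over the list alone). The median was 0.56 (camera adjusted p = 0.00037; adjusted p = 0.87 with an estimated correlation; exact permutation p = 0.057). The list mean was 3.76, 3.28, 3.33 and 3.8 in the mutator 1 and 2 pair and replicates 3 to 5, and 2.87 to 3.26 in wild-type samples. The primitive endoderm mean described below was also highest in the pair and in mutator replicate 5, so a share of other cell types may contribute. Besides Hexa, those that rose included Lamp2, a lysosomal membrane protein gene, from 10.8 ± 0.992 to 27.7 ± 9.88 FPKM, Ctsd, for cathepsin D, from 30.3 ± 6.95 to 71.5 ± 22.4 FPKM, and Wipi1, from 0.92 ± 0.267 to 3 ± 1.31 FPKM. Of 27 p53 targets 2 rose (2 adjusted over the list alone). The list median was 0.52, with 23 of 27 members above 0 (camera adjusted p = 0.00037; adjusted p = 0.87 with an estimated correlation). The genes that rose were Cdkn1a, the gene of the cyclin-dependent kinase inhibitor p21, from 5.1 ± 1.24 to 9.6 ± 1.26 FPKM, and the death receptor gene Tnfrsf10b, from 2.72 ± 0.661 to 7.64 ± 2.94 FPKM. Under TPM 10 lysosome genes and 8 p53 targets rose, and with median-of-ratios size factors 9 and 6. The p53 list mean lay above all wild-type samples in 3 of 4 mutator samples and did not in mutator replicate 3, at 2.88 against 2.88 to 3.13 in wild type (exact permutation p = 0.229). Of 26 integrated stress response targets Cebpb and Vldlr rose (6 higher and 1 lower adjusted over the list alone). The list median was 0.27 (camera adjusted p = 0.035; adjusted p = 0.87 with an estimated correlation; exact permutation p = 0.343). Of 23 immediate early and heat shock genes, a check on RNA handling, Klf6 and Jun rose and the chaperone genes Dnaja1 and Hsph1 fell (9 higher and 3 lower adjusted over the list alone). The median was 0.55 (camera adjusted p = 0.041; adjusted p = 0.87 with an estimated correlation; exact permutation p = 0.4).

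Marker lists of other cell types went both ways. Of 32 feeder fibroblast markers tested, 31 were above 0 and 1, Cyr61, rose (1 adjusted over the list alone). Their median was 0.68 (camera adjusted p = 1.2e-05; adjusted p = 0.87 with an estimated correlation; exact permutation p = 0.114). Of 24 primitive endoderm markers, 14 passed the filter on the mean over all 8 libraries, which can favour genes high in mutator libraries. All 14 were above 0, and 0 passed in limma over all genes or adjusted over the list alone. Gata6 and Sox17, endoderm genes outside the rule and below the filter, measured 2.1 and 1.11 FPKM in mutator replicate 5. They measured 0.12 to 0.26 and 0.09 to 0.28 FPKM in the other mutator libraries. In wild type they measured 0.08 to 0.11 and 0.0 to 0.56 FPKM. Under TPM 5 of 14 endoderm and 7 of 32 feeder markers rose, and with array weights 3 and 4. The endoderm median was 1.11 (camera adjusted p = 9.7e-05; adjusted p = 0.87 with an estimated correlation). Pdgfra measured 0.379 ± 0.113 FPKM in wild-type and 2.56 ± 1.47 FPKM in mutator samples and Thbd 0.566 ± 0.228 and 2.73 ± 1.73 FPKM, with limma adjusted p of 0.064 and 0.09. The endoderm list mean was 4.6 in mutator replicate 5, 2.4 to 3.34 in the other mutator samples and 2.02 to 2.18 in wild-type samples (exact two-sided permutation p = 0.057). The 11 trophectoderm markers had a median of 0.6 with 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.048; adjusted p = 0.87 with an estimated correlation; exact permutation p = 0.229). Tead4 and Krt19 measured 4.19 ± 1.04 and 4.88 ± 3.22 FPKM in mutator and 2.38 ± 0.0585 and 1.47 ± 1.17 FPKM in wild-type samples. Of 8 neuroectoderm markers Nes rose and Tubb3 fell (1 higher and 3 lower adjusted over the list alone), with a median of -0.42 (camera adjusted p = 0.19). The 3 tested mesoderm markers had a median of 0.1 (camera adjusted p = 0.84; 0 past the threshold adjusted over the list alone), with limma adjusted p of 0.35 for Bmp4 and 0.38 for Nkx2-5.

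Pluripotency genes went both ways. Of 30 naive pluripotency genes, Dppa2, Nr0b1 and Tet2 fell, Tbx3 rose and 26 did not pass (1 higher and 5 lower adjusted over the list alone). The list, with a median of -0.38, was not called (camera adjusted p = 0.065). Under TPM its median was 0.12, or -0.25 relative to the median of all genes. Nr0b1 fell from 28.8 ± 1.47 to 15.4 ± 3.34 FPKM and Tet2, for an enzyme that oxidizes methylcytosine, from 23 ± 0.927 to 13.2 ± 2.56 FPKM, while the T-box factor gene Tbx3 rose from 4.06 ± 0.465 to 12.2 ± 5.3 FPKM. Among 12 primed epiblast genes Dnmt3a was the 1 that fell (1 adjusted over the list alone; median -0.64; camera adjusted p = 0.3).

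Other metabolic lists were not called, with some single genes past the threshold. Of 24 glycolysis genes Slc2a3, the glucose transporter GLUT3 gene, rose from 71.3 ± 18.3 to 238 ± 82 FPKM. Ldhb rose from 16.2 ± 5.19 to 44 ± 9.8 FPKM and Eno2 from 0.41 ± 0.211 to 2.28 ± 1.04 FPKM (4 higher adjusted over the list alone). The glycolysis list had a median of -0.1, a mean of 0.09 and a camera adjusted p of 0.47. Of 24 serine and one-carbon genes 2 fell, Mat2a among them (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.27). Hspd1, for the mitochondrial chaperonin HSP60, fell from 191 ± 30.9 to 87.8 ± 24.4 FPKM, the 1 of 19 mitochondrial chaperone and protease genes to fall (2 adjusted over the list alone; camera adjusted p = 0.083). Prdx1 among 27 antioxidant genes fell from 448 ± 37.5 to 223 ± 32.5 FPKM (1 adjusted over the list alone; camera adjusted p = 0.065). Tfrc, the transferrin receptor gene, among 22 iron genes fell by 1.18 on the log2 scale (1 adjusted over the list alone; camera adjusted p = 0.61). Srebf2 among 22 cholesterol genes rose by 1.03 (1 adjusted over the list alone; camera adjusted p = 0.17). In the TCA cycle list 0 of 21 genes passed over all genes, and 1 higher and 3 lower did adjusted over the list alone. Idh2 had a log2 change of 1.4 and Pdhx of -0.84, with limma adjusted p of 0.05 and 0.056 (camera adjusted p = 0.41).

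Of 23 imprinted genes Igf2r and the noncoding Airn, which overlap in part, rose by log2 changes of 1.31 and 0.99 (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.5). Without a known strand setting, reads from the part they share cannot be told apart. Stk31 and Sycp1 fell among 18 germline genes, by 0.74 and 0.86 on the log2 scale (3 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.39). In limma, 0 of 10 interferon and nucleic acid response genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.5), with log2 changes of -0.88 for Ddx58 and 0.86 for Bst2 at adjusted p of 0.06 and 0.19. Of 79 cytosolic ribosomal protein genes Rpl10l, a retrogene copy of Rpl10, fell (1 adjusted over the list alone; camera adjusted p = 0.57).

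Y-linked transcripts differed between mutator lines. Ddx3y measured 19.9, 6.31 and 10.2 FPKM in wild-type replicates 1 to 3 and 1.47, 1.37, 8.14, 0.36 and 9.64 FPKM in mutator replicates 1 to 5. Xist, the RNA of the inactive X chromosome, measured 2.02, 2.83 and 3.56 FPKM in the wild-type and 4.93, 5.07, 3.48, 5.3 and 2.66 FPKM in the mutator libraries, with a limma adjusted p of 0.27. The 5 tested sex-linked genes had 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.47), Uty having a log2 change of -1.93 at a limma adjusted p of 0.2.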

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

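All tests of explanations in this part were chosen after the results were seen. Of 143 named genes and list means, 3 had a mutator sample far from the other mutator samples, and chance alone would give about 7.2. mt-Atp8 was 12.7 FPKM in mutator replicate 3 and 26.1, 28.5 and 27.1 FPKM in the others, a gap of 0.887 of the range on the log2 scale. mt-Co3 was 3.09 FPKM in mutator replicate 3 and 4.89 to 5.32 FPKM in the others, a gap of 0.838. The mean of the mitochondrial ribosomal protein list was 3.76 in mutator replicate 5 and 3.27 to 3.34 in the others, a gap of 0.843. List means were not scaled between libraries beyond FPKM. The median FPKM of genes with a mean of at least 1 was also highest in mutator replicate 5. It was 5.807 there and 4.645 to 4.833 in the other mutator libraries.

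For the number of genes called, 1 of the 35 splits of the 7 samples into 4 and 3, the real one, gave as many. That is the smallest share that 35 splits allow. It argues against a random grouping of the samples. It cannot tell genotype from a shared origin of the wild-type lines, which may come from 1 embryo. Among genes with no missing value, the real split called 894 genes, 353 higher and 541 lower, and the highest of the other splits called 48, 9 and 39; for the higher and for the lower genes too, 1 of 35 splits reached the real count. Chance cannot be excluded for the number of lists called by camera at the preset correlation: 13 of 35 splits called at least the 15 of the real split, and the highest other called 21.

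The lower transcripts of the mitochondrial ribosomal, DNA replication and G1 to S lists, 139 tested members with a median log2 change of -0.62 and quartiles of -0.79 and -0.37, were set against 3 technical explanations. A trend with transcript length and GC content exists across genes (Spearman's rho 0.23 and 0.26; genes are not independent replicates), but with that trend removed the median was -0.5 and the upper quartile -0.28, which argues against it as the whole cause. With the feeder marker mean as a covariate, the median was -0.42 with an upper quartile of -0.22, and single genes lost their calls. That mean was above all wild-type samples in 3 of 4 mutator samples, so the covariate overlaps with genotype and cannot decide on feeder cells. In mutator replicate 4 it was 2.47, within the wild-type range of 2.17 to 2.6, and the 3 list means were still below wild type. The cells had been moved off feeders, and Col1a1 reached at most 24.4 FPKM in mutator and 4.95 FPKM in wild-type libraries. Primitive endoderm and neuroectoderm markers moved apart by 1.53, with quartile ranges over genes that did not overlap (0.97 to 1.59 and -0.66 to -0.15). This argues only against a lower share of pluripotent cells with all other cell types raised alike. A lower share with endoderm-type or feeder cells alone in their place stays open. The endoderm mean, over 14 of the 24 list genes, was above all wild-type samples in 4 of 4 mutator samples. Gata6 and Sox17, below the filter, exceeded 1 FPKM only in mutator replicate 5. Genotype is a hypothesis that may account for the pattern, untested against differences between embryos or lines, and for the 43 ATP synthase and complex II to IV genes the length and GC trend may account for most of it, as their median moved from -0.43 to -0.17 when it was removed.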

How the results depend on the processing

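Settings chosen after seeing the data were the 8 libraries counted separately, leaving out the mutator 1 and 2 pair, Y-linked expression as a covariate, removal of the length and GC trend, leaving out small RNA genes, and protein-coding genes only. For the 895 genes changed (353 higher, 542 lower) the limma counts that moved by more than 1.5 times are given as changed, higher and lower. There were 2203, 906 and 1297 with 8 libraries counted separately, 2150, 966 and 1184 with median-of-ratios size factors, and 3618, 1728 and 1890 with array weights, which gave wild-type replicate 2 a weight of 9.21. Quantile normalization gave 1453 with 647 higher, small RNA genes left out 1345 with 572 higher, and protein-coding genes only 1506 with 694 higher. Removing the length and GC trend gave 556 higher genes, with 651 of the 895 shared. A minimum of 5 FPKM, which left 6221 genes tested in place of 11949, gave 188 higher genes. TPM gave 1092 higher and 21 lower. With no filter, which adds low genes to reach 27027 tested, there were 4 (1 and 3), and with the feeder list as covariate 2 (1 and 1). With Y-linked expression as covariate there were 0, 0 and 0, at 2625 genes with an unadjusted p below 0.05. Leaving out 1 replicate gave 2 to 1096 changed genes, 1 to 581 higher and 1 to 524 lower: 5 (1 and 4), 2 (1 and 1) and 2 (1 and 1) without wild-type replicates 1, 2 and 3, 241 (134 and 107) and 581 (156 and 425) without mutator replicates 4 and 5, and 5 without the pair (3 higher and 2 lower), where fewer samples were fitted. Without mutator replicate 3 the higher genes were 581. Apart from those left with fewer samples or more genes tested, the cause was not tested.

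Replicate numbers do not pair the samples, and with the replicate block 1 gene was called (0 higher and 1 lower) at 2 residual degrees of freedom. Of the same-numbered pairs, 0 had a correlation above 0.1 and not every sample correlated best with its own number. DESeq2 was not run, as the table used held FPKM. The 15 lists called became 0 with an estimated correlation (lowest adjusted p = 0.87) and 0 with fry (lowest adjusted p = 0.2). They became 14 to 18 on leaving out 1 replicate and 13 without the mutator 1 and 2 pair. Mitochondrial ribosomal, mtDNA replication, nucleotide pool, DNA replication, G1 to S, p53, primitive endoderm and lysosome lists kept their calls in all other settings. The lists for ATP synthase, trophectoderm, integrated stress response and immediate early genes lost them in 5 or more. Of 78 called genes followed, 0 changed direction, and all lost their call without a wild-type replicate, with no filter, with the block and with either covariate. Under TPM 43 of 78 lost it, and 77, 54 and 30 did without the mutator 1 and 2 pair, mutator replicate 4 and mutator replicate 5.

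Polg, 0.07, was -0.06 with array weights, -0.17 with the feeder covariate and -0.24 with the length and GC trend removed, and 0.0 to 0.2 on leaving out 1 replicate. These and the following turned in direction, none past the threshold in either setting except the feeder list itself, -0.08 with its own mean as covariate. For lists, the direction is that given by camera relative to the other genes. The values given for lists are median log2 changes, some of which keep the sign of the main fit. Under TPM the results that turned were mt-Atp8 0.37, mt-Co1 0.2, mt-Nd1 0.01, mt-Nd3 0.32, mesoderm 0.32 and histones 0.65. Under quantile normalization they were mt-Atp6 -0.03, mt-Atp8 0.12, mt-Co1 0.26, complex I 0.01, TCA cycle 0.12, mesoderm -0.04 and cytosolic ribosomal proteins 0.1. With the feeder covariate they were mt-Atp8 0.29, mt-Nd3 0.37, complex I 0.03, serine and one-carbon 0.09, glycolysis -0.18, TCA cycle 0.19, mesoderm -0.32 and cytosolic ribosomal proteins 0.17. With the trend removed they were Nkx2-5 -0.02, mt-Atp8 0.61, mt-Co1 0.14, mt-Nd1 0.09, mt-Nd3 0.7, mesoderm -0.2, germline 0.0 and cytosolic ribosomal proteins 0.09. With the Y-linked covariate they were Uty 0.02, Ddx3y 0.02, mt-Atp6 -0.24, mt-Co2 -0.32, mt-Co3 -0.15, mtDNA-encoded -0.22, iron handling 0.18, primed epiblast -0.04 and mesoderm 0.02. With the replicate block they were mt-Atp6 -0.1, mt-Co2 -0.09, mt-Nd2 -0.05, mt-Nd3 0.15 and histones -0.26. With array weights they were mesoderm 0.04 and cytosolic ribosomal proteins 0.02, with no filter interferon 0.06 and histones 0.11, with 5 FPKM cytosolic ribosomal proteins -0.11, with protein-coding genes imprinted -0.07, and with 8 libraries mt-Nd3 0.14. On leaving out 1 replicate the ranges of those that turned were -0.08 to 0.25 for mt-Atp6, -0.28 to 0.14 for mt-Atp8, -0.12 to 0.33 for mt-Co2, -0.03 to 0.18 for mt-Co3, -0.6 to 0.38 for mt-Nd3, -0.05 to 0.23 for mtDNA-encoded genes, -0.28 to 0.17 for glycolysis, -0.02 to 0.26 for mesoderm, -0.28 to 0.65 for histones and -0.26 to 0.15 for cytosolic ribosomal proteins. These ranges, and that of Polg, include the fit without the mutator 1 and 2 pair. The cause of the changed directions was not tested. Without counts, depth sets no interval on single values.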

Other observations

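All tests in this part were chosen after the results were seen, and the genes in it were picked after their values were known. In the zinc-finger block on distal chromosome 4, 19 of 21 tested genes fell, and elsewhere 513 of 11770 genes with a position did. Of 652 windows of 3 Mb with at least 5 tested genes, 4 held more lower calls than expected after adjustment and 0 more higher calls (hypergeometric test, which treats genes as independent). Both windows of the chromosome 4 block were among the 4, with 11 of 41 and 11 of 58 genes lower. Another was on chromosome 2 from 177 to 180 Mb, with 8 of 22 genes lower (adjusted p = 0.00097), among them Zfp931 and the predicted genes Gm14401, Gm14403 and Gm14406. The last was on chromosome 1 from 57 to 60 Mb, with 8 of 25 lower (adjusted p = 0.0019), SNORD70 and Orc2 among them.

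Loss of a chromosome segment that reaches past the block is argued against by the 41 protein-coding genes in the 3 Mb on either side, whose median log2 change was 0.25 with 1 lower and 4 higher calls, and by 6 genes between these and the block with a median of 0.21. No other tested protein-coding gene lay within the block. These paralogs share sequence, so reads could move between them, but the summed FPKM of the 21 genes was 414 ± 1.7 (SD, n = 3) in wild-type and 144.8 ± 22.7 (SD, n = 4) in mutator samples, a ratio of 0.35 with no overlap. With the length and GC trend removed the median was -0.97, and 12 of 21 genes were called. A deletion or another haplotype confined to the block, shared by the mutator lines, and altered regulation of the cluster stay open, since no strain or genotype of the region was given. The hypothesis that numbered zinc-finger genes elsewhere were lower more often held as deposited (22 of 248 against 420 of 10063 other protein-coding genes, odds ratio 2.23, Fisher's exact test p = 0.0012) but not with the length and GC trend removed (21 of 246 against 685 of 10049, odds ratio 1.28, p = 0.31). As lower calls rose mainly among the other genes, and the zinc-finger median moved from -0.2 to -0.12, it remains undecided.

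Eif2s3y measured 47.8 to 94.4 FPKM in the wild-type libraries, 65.3 and 52.4 FPKM in mutator replicates 3 and 5, and 3.76, 4.14 and 0.96 FPKM in mutator replicates 1, 2 and 4. Uty measured 13.9 to 26.4 FPKM in the wild-type libraries, 16.5 and 14.1 FPKM in mutator replicates 3 and 5, and 0.6, 0.92 and 0.29 FPKM in mutator replicates 1, 2 and 4.

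Pou5f1, the gene of OCT4, measured 291, 239 and 258 FPKM in the wild-type and 103, 103, 138, 162 and 188 FPKM in the mutator libraries, a log2 change of -0.85 that did not pass in limma (adjusted p = 0.072). Sox2 measured 61.8 to 74.3 and 58.6 to 79.2 FPKM. Col4a1 measured 50.1 FPKM in mutator replicate 5, 2.13 to 7.46 FPKM in the other mutator libraries and 1.29 to 1.8 FPKM in wild type. The fibroblast collagen gene Col1a1 measured 24.4 FPKM in mutator replicate 3, 3.75 to 10.9 FPKM in the other mutator libraries and 1.83 to 4.95 FPKM in wild type. On the second principal component wild-type replicate 1 and mutator replicate 5 lay together at 40.2 and 33.7, the others between -46.9 and -5.07. The same pair had the highest means of the cytosolic ribosomal protein list, 8.31 and 8.27, against 7.14 to 7.66 in the other samples. Wild-type replicate 1 and mutator replicate 5 also had the highest median FPKM of genes with a mean of at least 1. These medians were 5.516 and 5.807, against 4.581 to 4.833 in the other libraries.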
